A study of Mus musculus with 12 samples.

How the data were processed

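RNA of magnetically purified bone marrow monocytes and macrophages had been measured on 12 mouse whole-transcriptome arrays, 1 per mouse. The deposited values were log2 intensities summarised by the authors per transcript cluster. Expression Console and RMA are named per the submitters' processing notes, with no version stated. The values did not exceed 19.93, and the arrays' quantiles were not identical. The table held 72688 features, of which 6732 control features were left out, leaving 65956 transcript clusters. Scanner files were not used here. For arrays, their number limits the precision.

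Symbols came from the platform's gene table: 31258 clusters had 1 symbol, 1492 had several and 33206 had none, which gave 30702 symbols. 1152 older symbols were updated, 31256 annotated clusters had their symbol in a RefSeq table, 441 genes had more than 1 cluster, and 1188 clusters held values identical to another. A cluster was tested if it lay above the array's own median in at least 3 arrays, which 37240 did, 19489 of them named genes taken once each.

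The groups followed the labels: mice with and without MEC1 at 21 and at 31 days, 3 of each, with mouse numbers marking separate animals. The tests of transcript clusters and of gene lists were fixed before the data were examined. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, and contrasts were moderated by empirical Bayes. The contrasts were MEC1 against control at each day, their average, their difference, and 31 against 21 days with and without MEC1. Two-sided p-values were adjusted by Benjamini-Hochberg over the tested clusters with a threshold of 0.05. Spike-in controls (4 hybridisation and 4 poly-A) and mitochondrial transcripts were compared by exact permutation tests, two-sided, which were not part of that plan. For these tests 0.1 is the smallest p with 3 against 3 mice. For the average, labels were permuted within days, and the smallest p is 0.005.

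The named genes were, for each MEC1 comparison, the 12 largest rises and 12 largest falls that passed with non-overlapping groups, with 1 symbol and not of the predicted-gene class. For the difference and the time comparisons the limit was 6 in each direction, filled to 5 by smallest p where fewer than 5 passed. Up to 4 members of each list, 6 non-coding genes, and fixed cell identity and B cell genes were added. Lists of 26 gene groups, covering interferon response, antigen presentation, macrophage and monocyte states, metabolism, stress, proliferation, other marrow cell types and non-coding RNAs, were tested with camera at its preset correlation of 0.01 on 1 cluster per gene. Camera with an estimated correlation and fry were run beside it, and Benjamini-Hochberg was applied over the lists of a contrast.

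The alternatives were no filter or one at the 70th percentile, quantile normalization, centring on the array median, array weights, empirical Bayes with trend and robust, the 6 arrays of a comparison alone, 1 cluster per gene or their average, a 1.5-fold minimum, no moderation, and leaving out each array in turn. The hybridisation-control level as a covariate, quantile normalization without MEC1 31 d replicate 3, and comparison with 10000 random lists of matched level were added after seeing the data. The fit was tested on simulated data. Changes of log2 1, 2 and 3 were recovered in 37.3%, 77.6% and 93.9% of clusters at 21 days with 8 false calls (5.44%). At 31 days they were recovered in 28.4%, 76.1% and 93.9% with 10 (7.04%), and for the average in 67.2%, 95.5% and 98.5% with 5 (2.79%). The simulation had independent noise, the same spread in all groups, few changed clusters and no shift of whole arrays. Its rates therefore do not carry over to arrays that differ as a whole between groups.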

Results

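Monocytes and macrophages were purified magnetically from the bone marrow of 12 mice, and their RNA was read on a whole-transcriptome mouse array, 1 array per mouse. The animals carried no functional Rag2 or common gamma chain on a BALB/c background, so that they lacked T, B and natural killer cells and accepted human cells. MEC1, a human B cell line derived from chronic lymphocytic leukemia, had been injected intravenously into 6 of them, and 6 age-matched mice had received none. Tissue was taken at 21 days, early in the disease, from mice aged 11 weeks, and at 31 days, late in the disease, from mice aged 13 weeks. Each day gave 3 mice with MEC1 and 3 without. The arrays held 65956 transcript clusters, of which 37240 were bright enough to be tested, and the small number of arrays limits the precision of every value. The question was which coding and non-coding transcripts of these cells changed as the leukemia advanced.

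Several monocyte and macrophage genes had high probe intensities in all 4 groups, although levels of different probes do not rank abundance. These levels also do not measure purity: neutrophil and erythroid gene lists had median levels of 11 and 10.14 in control mice at 31 days. Lyz2, which encodes lysozyme, stood at a log2 intensity of 19.34 ± 0.04 in control mice and 18.60 ± 0.261 in MEC1 mice at 21 days, and at 19.33 ± 0.06 and 17.61 ± 1.26 at 31 days (SD, n = 3 mice per group). Csf1r, the receptor for the macrophage growth factor CSF1, lay at or above the 95th percentile of every array, while the IgG receptor Fcgr1 lay lower, between the percentiles 67.9 and 89.1. With MEC1 at 31 days, Csf1r fell by 1.51 on the log2 scale (SE 0.339, adjusted p = 0.00646, limma) and the lysosomal gene Cd68 fell by 2.49 (SE 0.437, adjusted p = 0.00206). Itgam, Adgre1 and Ly6c2 fell by 1.14, 1.52 and 1.61 on the same day, with adjusted p of 0.0158, 0.0176 and 0.026. None of these 5 genes passed at 21 days. Lyz2 and Ly6c2, at 19.41 for the latter in control mice at 31 days, stood near the highest value of any array, 19.93, where probes may saturate, so that their falls may be larger than the values here. The fall of Itgam was close to the median change of -0.98 of all clusters at its level, from 12 to 14. The fall of Adgre1 at 31 days did not pass with quantile normalization (log2 change -0.95, adjusted p = 0.13) or without MEC1 31 d replicate 3 (-0.99, adjusted p = 0.0507) or control 31 d replicate 3 (-1.34, adjusted p = 0.0617). That of Ly6c2 did not pass when any 1 of the 3 control arrays at 31 days was left out (adjusted p of 0.0605, 0.0621 and 0.063). Without MEC1 31 d replicate 3 the log2 changes of Ly6c2 and Itgam were -0.85 and -0.68. The fall of Ly6c2 did not pass without moderation either (adjusted p = 0.0551), and with only the 6 arrays of the day neither Ly6c2 nor Itgam passed (0.0775 and 0.0588). With quantile normalization without MEC1 31 d replicate 3, Itgam and Adgre1 had changes of -0.45 and -0.49 that did not pass (0.121 and 0.419). With the hybridisation-control level as a covariate, most of whose variance lay between the groups, all 5 changes at 31 days turned positive and none passed: 1.01 for Csf1r, 0.48 for Cd68, 1.18 for Itgam, 0.59 for Adgre1 and 2.94 for Ly6c2.

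The arrays of MEC1 mice also differed as a whole from those of control mice. The 4 bacterial hybridisation controls, which are added in fixed amounts, had a mean log2 intensity of 10.81 ± 0.0869 in control mice and 11.92 ± 0.118 in MEC1 mice at 21 days, and of 10.62 ± 0.128 and 12.57 ± 0.54 at 31 days (SD, n = 3). Averaged over both days the difference was 1.53, with an exact stratified permutation p = 0.005, the smallest that 3 mice per group on each day allow. The poly-A controls, added before labelling, were higher by 0.864 (exact p = 0.005). Mitochondrial transcripts were lower by 0.682 at 21 days and by 1.80 at 31 days, where the exact test within 1 day cannot fall below p = 0.1, and by 1.24 averaged over both days (exact p = 0.005). The array median rose by 0.20 at 21 days and by 0.43 at 31 days, so that changes of about that size in dim transcripts do not exceed the shift of the whole array. MEC1 31 d replicate 3 stood farthest out, with hybridisation controls at 13.18 and a mitochondrial median of 6.135.

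**Figure D1:**
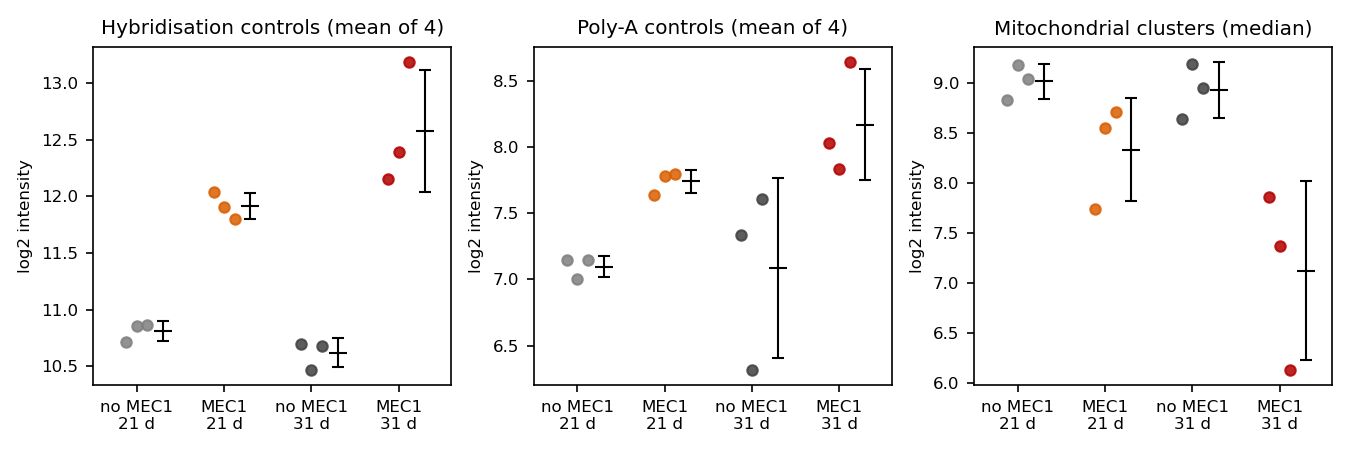
Log2 intensity of the hybridisation controls (mean of 4), the poly-A controls (mean of 4) and the mitochondrial clusters (median) on each array, by group. Points are arrays and bars are the mean and SD of 3 mice; the hybridisation controls averaged 12.57 in MEC1 mice at 31 days and 10.62 in control mice.

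At 21 days, early in the disease, the genes with the largest falls in MEC1 mice included transporters, lectins and red cell genes. Abca9, a lipid transporter of macrophages, fell by 3.35 on the log2 scale (SE 0.232, adjusted p = 0.000185), and Cyp27a1, which oxidises cholesterol, fell by 3.49 (SE 0.352, adjusted p = 0.00148). Cd209a, a lectin of monocyte-derived dendritic cells, fell by 3.58 (SE 0.337), the beta-glucan receptor Clec7a by 3.01 (SE 0.384) and the lectin Clec4a1 by 2.87 (SE 0.375). Trf, the iron carrier transferrin, and Irs2, an adaptor of the insulin receptor, each fell by 3.26, while Thbs1, the matrix protein thrombospondin 1, fell by 4.17 and the kinase gene Sik1 by 3.06. The red cell genes Aqp1 and Slc4a1 fell by 4.56 and 4.05, and Alas2, the first enzyme of heme synthesis in red cells, by 2.87.

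The rises at 21 days were led by small structural RNAs. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle whose clusters held identical values, rose by 5.72 (SE 0.764, adjusted p = 0.0051). The Y RNAs Rny3 and Rny1 rose by 3.30 and 2.68, the U1 spliceosomal RNA Rnu1a1 by 2.55, the 5S ribosomal RNA gene n-R5s25 by 2.00, and the microRNA precursors Mir16-2, Mir15b and Mir103-2 by 3.59, 2.85 and 2.68, the last 2 from control levels near the array median. Saa3, an acute-phase serum amyloid made by activated macrophages, rose by 2.37 (SE 0.467, adjusted p = 0.0247). Il1f9, a cytokine of the interleukin 1 family, rose by 2.05 (SE 0.486, adjusted p = 0.043), and the T cell receptor segment Traj14 rose by 2.74 (SE 0.687, adjusted p = 0.0499).

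In the test over all clusters at 21 days, 1615 of 37240 (4.34%) changed, 681 upward and 934 downward, at a Benjamini-Hochberg adjusted p under 0.05. The count rested on few arrays: it was 333 without MEC1 21 d replicate 1, 347 without replicate 2 and 2875 without replicate 3, 1054, 464 and 391 without control 21 d replicates 1, 2 and 3, and 762 and 2700 without control 31 d replicate 3 and MEC1 31 d replicate 3. Of the 24 genes named above for this day, 13 passed in each of the 12 fits that left out 1 array. Rny3, Mir15b, Traj14, Mir103-2, Rnu1a1, Saa3, Il1f9, n-R5s25, Aqp1, Slc4a1 and Alas2 did not, with adjusted p of up to 0.155, and Mir15b, Traj14 and Mir103-2 did not pass with quantile normalization either (0.0731, 0.0815 and 0.0687). Quantile normalization gave 608 rises and 458 falls, the 6 arrays of that day alone 454 changed clusters, and a fit with the hybridisation-control level as a covariate, 92.1% of whose variance lay between the 4 groups, gave 4. Array weights gave 15923.

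Among 26 gene lists fixed before the data were examined, 2 moved against the other genes at 21 days. All 13 measured erythroid genes had negative changes (median -2.42), of which 6 passed over all clusters and 13 adjusted over the list alone (camera, adjusted p = 3.82e-08; adjusted p = 0.654 with an estimated correlation). The immediate-early genes, which handling and dissociation induce, had a median of -0.86, with 2 of 16 fallen and 6 adjusted over the list alone (adjusted p = 0.0022; adjusted p = 0.665 with an estimated correlation). That median was -0.40 without MEC1 21 d replicate 1, -1.41 without replicate 3 and 0.22 with the covariate (adjusted p = 0.95). The other 24 lists did not pass, though members of some did, and with quantile normalization non-classical monocyte and dendritic cell genes passed downward (adjusted p = 0.0197 each). Among resident macrophage genes 4 of 19 fell, led by the lipid carrier Apoe at -2.72 and the iron transporter Slc11a1 at -1.69, and adjusted over the list alone 1 rose and 4 fell. Of the 14 non-classical monocyte genes 5 fell, such as the fractalkine receptor Cx3cr1 at -1.56, and adjusted over the list alone 2 rose and 5 fell. The costimulator Cd86 fell by 2.31 among 13 genes of MHC class II presentation, of which 2 fell by either adjustment, and in the checkpoint list the inhibitory receptor Cd300a fell by 1.88 while Pilra rose by 1.75.

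At 31 days, late in the disease, the largest rises were those of Il1r2, Cxcl13, Traj14 and Saa3. Il1r2, the decoy receptor that captures interleukin 1, rose by 7.97 on the log2 scale, or 251-fold (SE 0.457, adjusted p = 2.01e-05), from a mean of 5.67 in control mice to 13.65 in MEC1 mice (n = 3 each, limma). Cxcl13, the chemokine that draws B cells into follicles, rose by 6.95 (SE 0.649, adjusted p = 0.000192) from a control mean of 3.79. That mean lay near the median of the arrays, so that its true change may be larger, although dim clusters also rose in general. Saa3 rose by 6.04 (SE 0.467, adjusted p = 8.5e-05), and Stfa2l1, a stefin of the cysteine protease inhibitors, by 4.77 (SE 0.361, adjusted p = 8.5e-05). Vcan, the matrix proteoglycan versican of classical monocytes, rose by 3.82 (SE 0.29), and the interferon-induced non-coding RNA AW112010 by 4.15 (SE 0.511). Traj14 rose by 6.15, and the small RNA genes Rnu6, Rn7s1, Rn7s2, Mir221 and Mir103-2 rose by 4.21 to 5.10. With the hybridisation-control level as a covariate Mir221 turned to -0.72 and Mir103-2 had a change of 0.92 (adjusted p = 0.925 and 0.912).

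The largest falls at 31 days were nearly all of red cell genes. The water channel Aqp1 fell by 9.10 (SE 1.06, adjusted p = 0.00044), the anion exchanger Slc4a1 by 8.53 (SE 0.836, adjusted p = 0.000213) and the Rh-associated glycoprotein Rhag by 8.84 (SE 1.19, adjusted p = 0.000636). The blood group genes Ermap, Kel and Rhd fell by 7.81, 6.67 and 6.57, the carbonic anhydrases Car2 and Car1 by 8.10 and 7.56, and Alad, an enzyme of heme synthesis, by 7.87. The tight junction gene Cldn13 fell by 7.72 and the carboxylesterase Ces2g by 6.16. Aqp1, Cldn13 and Rhd ended at means of 4.99, 4.72 and 4.94 in MEC1 mice, close to array medians of up to 4.40, so that their falls may be larger. Xist, the RNA that silences 1 X chromosome in female cells, fell by 5.63 (SE 1.44, adjusted p = 0.0114), from 15.49 ± 0.288 to 9.86 ± 4.05 (SD, n = 3), and the change was -3.44 without MEC1 31 d replicate 1. All 24 genes named for this day passed in each fit that left out 1 array.

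**Figure D2:**
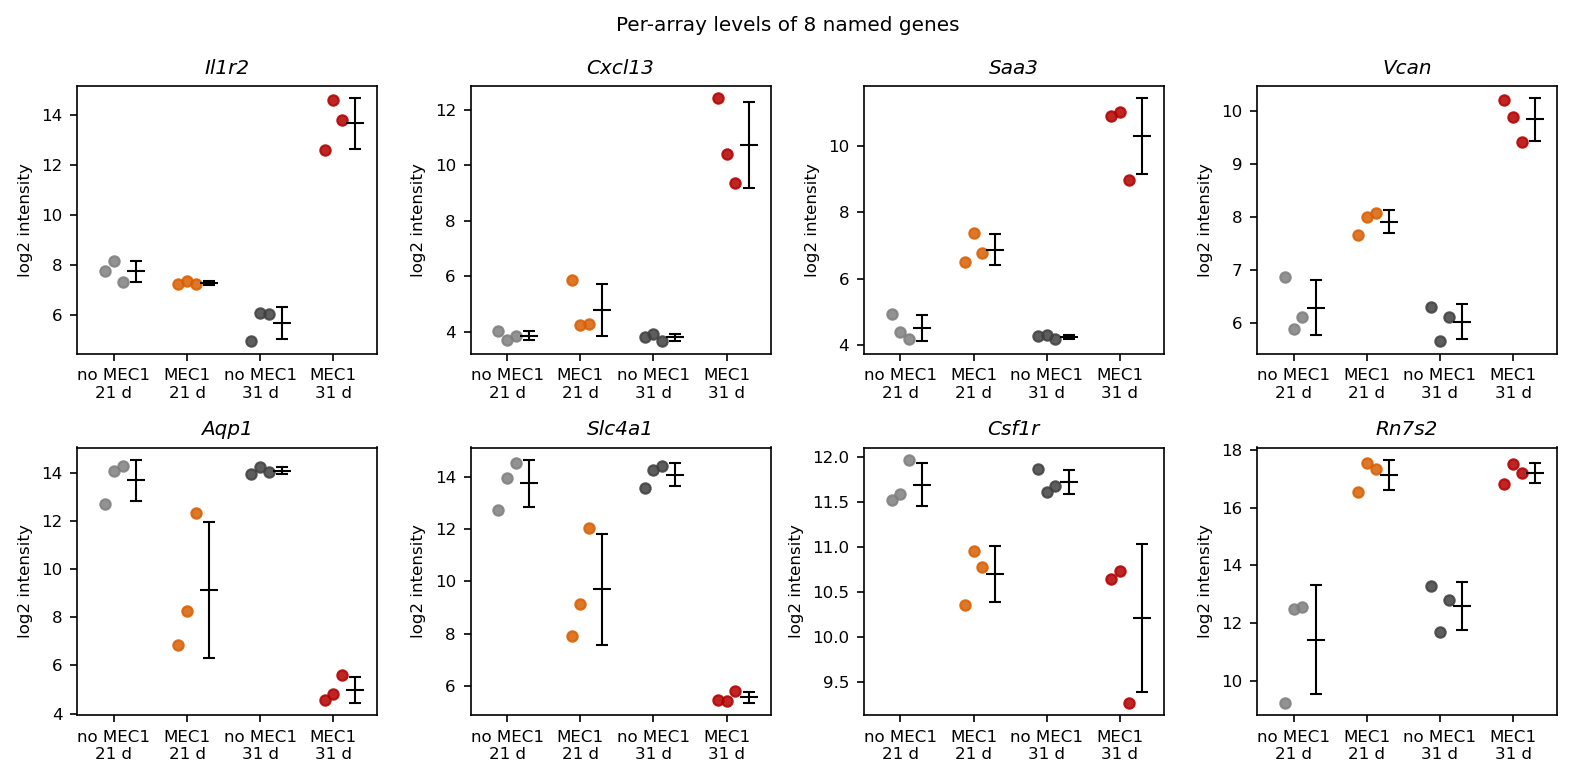
Log2 intensity of 8 named genes on each array, by group; points are arrays and bars show the mean and SD of 3 mice. Il1r2 and Cxcl13 stood at means of 13.65 and 10.74 in MEC1 mice at 31 days, while Aqp1 and Slc4a1 stood at 4.99 and 5.56 there. For Aqp1 and Slc4a1 the mean of MEC1 mice at 21 days lay between these and the controls. Il1r2 was not raised with MEC1 at 21 days.

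Over all clusters, 16297 of 37240 (43.8%) changed at 31 days, 8430 upward and 7867 downward, and 2818 rises and 5059 falls reached at least 2-fold. Of the 681 rises at 21 days, 639 (93.8%) were also called as rises at 31 days. Of the 934 falls, 788 (84.4%) were also called as falls. If the calls were independent, 154 and 197 would be shared. They were not independent, although the mice of the 2 days were different. Both sets of calls used 1 shared estimate of spread. The MEC1 arrays also differed as a whole in the same direction on both days. The overlap is therefore no separate replication. The direction of change followed the level of the transcript. Clusters at or below a log2 level of 4 in the control mice had a median change of 0.53 at 31 days (7775 clusters), and those between 10 and 12 one of -1.03 (1918 clusters). The split of rises and falls depended on the scaling and filter: centring arrays on their median gave 2785 rises and 13739 falls, quantile normalization 5026 and 5620, a filter at the 70th percentile 3046 and 7437, and no filter on dim clusters 21744 rises among 30065 calls. The count was 10556 without MEC1 31 d replicate 3 and 10656 without control 31 d replicate 2, and with the hybridisation-control level as a covariate 7 clusters were called, among them Saa3 (log2 change 9.91, adjusted p = 0.00822) and AW112010 (8.17, adjusted p = 0.045).

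**Figure D3:**
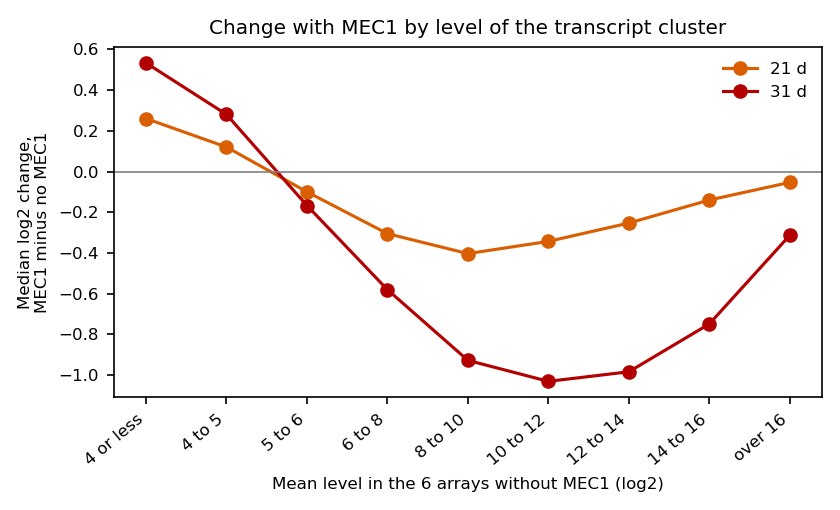
Median log2 change with MEC1 in bins of the mean level in the 6 control arrays, at 21 and 31 days. At 31 days the median was 0.53 for clusters at or below a level of 4 and -1.03 for those between 10 and 12.

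Of the 26 lists, 7 moved against the other genes at 31 days by camera with its preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.9 for each). All 13 erythroid genes fell, by either adjustment, with a median change of -3.98 (adjusted p = 1.53e-06). Epb42, a protein of the red cell membrane, fell by 3.59 and Alas2 by 4.74. All 30 proliferation genes fell, also adjusted over the list alone, with a median of -2.01 (adjusted p = 1.87e-07). The replication licensing genes Mcm2 and Mcm5 fell by 3.49 and 2.64, and the kinetochore motor gene Cenpe fell by 1.94. Of the 16 immediate-early genes 11 fell, or 12 adjusted over the list alone, with a median of -2.56 (adjusted p = 0.00103). The heat shock gene Hsph1 fell by 4.90 and the antiproliferative gene Btg2 by 2.61. Among 12 progenitor genes 8 fell by either adjustment (median -1.29, adjusted p = 0.0428), led by Gfi1b, a repressor of erythroid and platelet precursors, at -3.62, and by the stem cell marker Cd34 at -1.98 and the growth factor receptor Kit at -1.87.

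The medians of the remaining 3 calls lay inside the central 95% of random lists of matched level. Their percentiles were 8.925 for the unfolded protein response, 27.3 for interferon and 64.35 for T cell genes. In the unfolded protein response 10 genes fell and 1 rose of 16, or 13 and 1 adjusted over the list alone, with a median of -1.15 (adjusted p = 0.0266), or -0.67 without MEC1 31 d replicate 3. The transcription factor gene Atf3 fell by 2.72 and the chaperone gene Hspa5 by 1.62. Among type I interferon genes 11 of 32 fell by either adjustment (median -0.49, adjusted p = 0.0461), with the nucleotide kinase gene Cmpk2 at -2.59, the signal transducer Stat2 at -2.29 and the antiviral gene Rsad2 at -1.57. Of 9 T and natural killer cell genes, which these mice should lack in mature form, 5 rose and 1 fell by either adjustment (median 0.42, adjusted p = 0.0461), with the transcription factor genes Tbx21 at 1.17 and Eomes, whose control mean of 3.41 lay below the array median and leaves the size of its rise open. The interferon and T cell calls did not pass with quantile normalization (adjusted p = 0.133 and 0.42), and the T cell median was -0.01 with arrays centred on their median. With the hybridisation-control level as a covariate the medians turned to 0.80 for proliferation, 0.83 for the unfolded protein response and 0.88 for interferon genes, while immediate-early, progenitor and T cell genes had medians of -0.10, -0.30 and -0.04 that did not pass (adjusted p = 0.78, 0.281 and 0.863) and erythroid genes stayed at -3.40 (adjusted p = 1.7e-07). Of the members named, Mcm5, Cenpe, Atf3, Hspa5 and Stat2 turned to 0.14, 0.37, 0.14, 0.96 and 1.18, and none of these passed. The interferon call did not pass without control 21 d replicates 1 or 3 (adjusted p = 0.0565 and 0.0547), control 31 d replicates 1 or 2 (0.0639 and 0.0794) or MEC1 31 d replicates 2 or 3 (0.0774 and 0.157). The T cell call did not pass without the same arrays (0.0565, 0.0553, 0.0548, 0.0511, 0.0774 and 0.0634) or control 31 d replicate 3 (0.0755). The progenitor call did not pass without control 21 d replicates 1 or 3 (0.0548 and 0.0507), control 31 d replicate 1 (0.062) or MEC1 31 d replicate 2 (0.0774).

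Genes of macrophage programmes moved in both directions at 31 days, and none of their lists passed as a whole. Named genes in general moved both ways too: of 19489 tested, 4198 rose and 5661 fell. Counts of members near that share do not by themselves set a programme apart. Counts adjusted over the list alone equalled those over all clusters unless given. Among 21 inflammatory genes 5 rose and 6 fell, with the cytokine gene Il1b at 2.03 (SE 0.206) and the chemokine genes Ccl2 and Ccl3 at -2.84 and -3.71. The median of this list was 0.06 and its mean -0.30. In the alternative activation list of 18, 6 rose and 5 fell, with the matrix protease Mmp14 at 1.56, the chitinase-like Chil3 at 2.76 and the cytokine Tgfb1 at -2.14. Resident macrophage genes split into 7 rises and 6 falls of 19, with the complement gene C1qa at 1.49 and Apoe at -1.82. Among 18 interferon gamma genes 4 rose and 3 fell, with the transcription factor Irf8 at -2.62; the nitric oxide synthase Nos2 rose from a control mean of 3.43, below the array median, so that the size of its rise is open. For MHC class II presentation 2 rose and 5 fell of 13, with the costimulator Cd80 at 1.55 and the peptide loader H2-DMa at -1.64. Checkpoint genes gave 3 rises and 5 falls of 11, or 3 and 7 adjusted over the list alone, with Pilra at 2.61 and the inhibitory receptors Cd300a and Vsir at -2.09 and -2.17. Of 13 factors described as support for leukemic B cells 2 rose and 7 fell, with Cxcl13 the leading rise and the survival factor Tnfsf13b at -1.41. With the covariate Ccl3, Tgfb1 and Vsir turned to 1.07, 0.65 and 0.24, and none of these passed.

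Of 16 classical monocyte genes 2 rose, Vcan and Chil3, and 7 fell. Among 14 non-classical monocyte genes 3 rose and 6 fell, or 3 and 7 adjusted over the list alone, with Cx3cr1 at -2.27 and the integrin gene Itgal at -1.76. Hypoxia and glycolysis genes gave 5 rises and 3 falls of 22, with the glucose transporter Slc2a1 at 1.46 and the hexokinase Hk2 at -1.29. The median of this list was -0.06 and did not pass, but with quantile normalization it was 0.40 and passed (adjusted p = 0.0441). In cholesterol synthesis 4 of 17 fell, or 1 adjusted over the list alone, led by the regulator Srebf2 at -1.47. Osteoclast genes gave 1 rise and 3 falls of 7, with the acid phosphatase Acp5 at -1.97.

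Markers of other marrow cells also moved both ways at 31 days, as named genes in general did (4198 rises and 5661 falls of 19489). No further list of them passed on the deposited scale, while dendritic cell genes passed with quantile normalization (median -0.53, adjusted p = 0.0367). Among 22 neutrophil genes 4 rose and 7 fell by either adjustment: the stefin Stfa3 rose by 3.21, and Stfa1 and Stfa2 rose by 3.57 and 3.04. The control means of Stfa1 and Stfa2, 3.77 and 3.79, lay near the array median. Their rises may therefore be too low, or may include part of the general rise of dim clusters. Among 15 B cell genes 5 rose and 2 fell by either adjustment, with the transcription factor Pax5 at 2.23 (SE 0.164) and the immunoglobulin heavy chain gene Ighm at -4.54 (SE 0.383). Cd79a rose by 0.78 (adjusted p = 0.0186), but not with quantile normalization (0.40, adjusted p = 0.129), median centring (0.35, adjusted p = 0.119) or without MEC1 31 d replicate 3 (0.54, adjusted p = 0.0606), and it turned to -0.77 with the covariate. Its control mean of 3.71 lay below the array median. Cd79b had a log2 change of -0.18 that did not pass, and Ms4a1 was too dim to test. Of 14 dendritic cell genes 1 rose and 5 fell by either adjustment, with Cd209a at -3.72, the growth factor receptor Flt3 at -2.20 and the lectin Siglech at -2.45. Of 15 basophil, mast cell and eosinophil genes 7 fell by either adjustment, such as the protease Prss34 at -3.04, which turned to 1.91 with the covariate (adjusted p = 0.711). Of 11 platelet genes 1 rose and 1 fell by either adjustment, with the receptor subunit Gp9 at -1.19. Among 14 stromal and endothelial genes 2 rose and 2 fell, or 1 and 1 adjusted over the list alone, with the endothelial receptor Eng at -2.76, at a mean of 4.59 in MEC1 mice that also lay close to the array median.

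**Figure D4:**
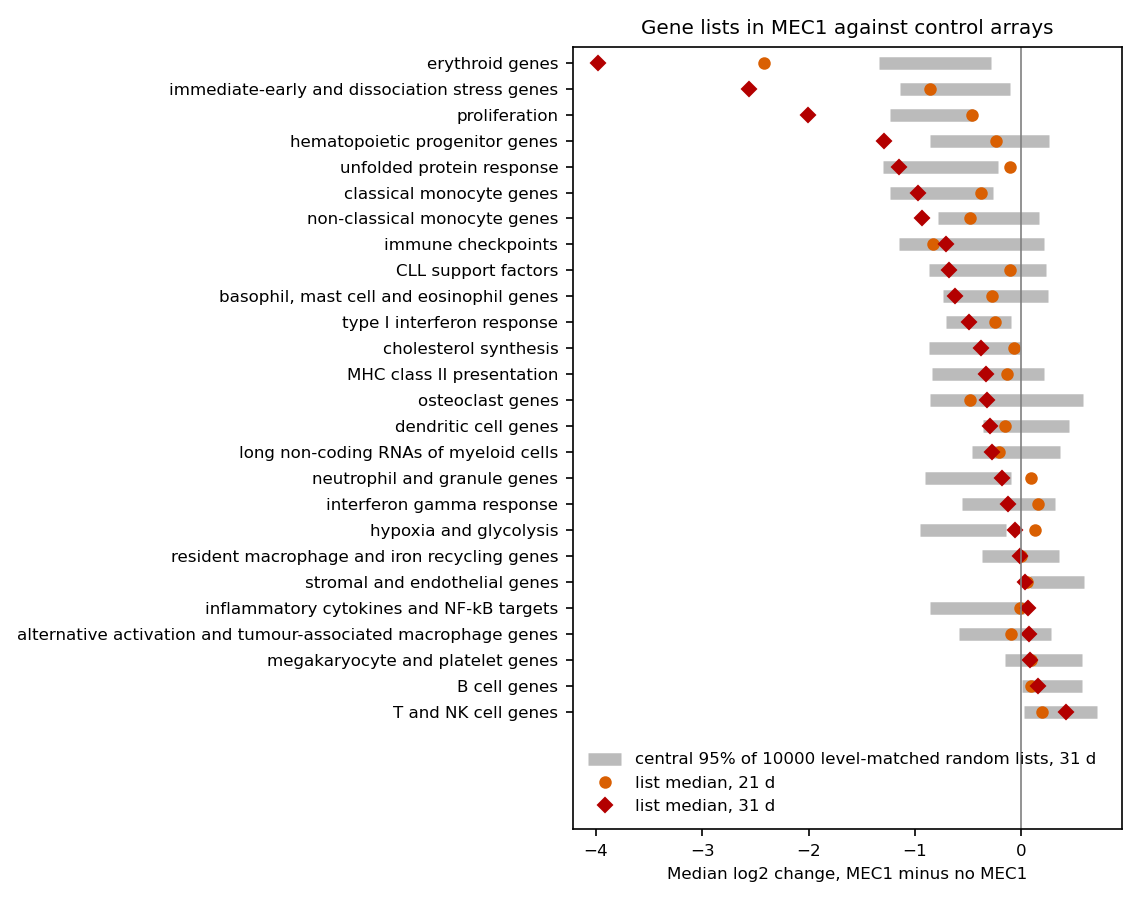
Median log2 change of 26 gene lists with MEC1 at 21 days (circles) and 31 days (diamonds); grey bars give the central 95% of medians of 10000 random lists of matched level at 31 days. The erythroid median was -3.98 and the proliferation median -2.01 at 31 days, both left of their grey bars.

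Classes of transcripts were counted apart at 31 days, with no test between them. Of 650 microRNA precursors 217 rose and 27 fell, with a median change of 0.48, or 0.43 with quantile normalization. Predicted genes gave 2196 rises and 463 falls of 5761 with a median of 0.39, which is below the array-median shift of 0.43. With quantile normalization they still gave 1557 rises and 389 falls, with a median of 0.23. The other named genes gave 1882 rises and 5211 falls of 13335 and a median of -0.37. Among 62 small nucleolar RNAs 9 rose and 12 fell, and 1 of 5 Snhg host genes fell. Of 16 long non-coding RNAs of myeloid cells 1 rose and 5 fell, or 2 and 6 adjusted over the list alone, and the list did not pass. Neat1 fell by 2.63 (adjusted p = 0.015), but did not pass without control 31 d replicate 2 (adjusted p = 0.0593) or MEC1 31 d replicate 3 (adjusted p = 0.0577), and turned to 2.66 with the covariate (adjusted p = 0.606). Averaged over both days, the microRNA precursors Mir6987, Mir544, Mir30c-1 and Mir451b rose by 1.59, 2.02, 1.48 and 1.27 (SE 0.141, 0.206, 0.165 and 0.142), the small nucleolar RNA Snora35 rose by 1.47 and Mir7067 fell by 1.66. Mir6987, Mir451b and Snora35 stood near or below the array median in control mice, so that the sizes of their rises are open. They may be larger, but dim clusters also rose in general. Clusters at or below a control level of 4 had a median change of 0.40 for the average.

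Averaging the 2 days, 6 mice with MEC1 against 6 without, brought out falls that were large at both times. Abca9 fell by 4.21 (SE 0.164, adjusted p = 4.78e-07), Trf by 3.55 (SE 0.212, adjusted p = 1.36e-05), Cd209a by 3.65 and Cyp27a1 by 3.58. The aspartic protease Ctse fell by 3.56, the erythroid membrane genes Ank1 and Tspan33 by 3.79 and 3.84, and the microRNA precursor Mir1938 fell by 3.60. Aqp1 and Slc4a1 averaged -6.83 and -6.29, Car1 -5.71 and Alas2 -3.81. Rises averaged 5.16 for Rn7s2, 4.44 for Traj14, 4.21 for Saa3 (SE 0.33, adjusted p = 4.13e-05), 3.94 for Cxcl13, 3.89 for Rnu6, 3.55 for Mir16-2 and Mir221, 3.44 for Mir103-2, 3.11 for Rnu1a1 and 2.87 for Stfa2l1 and Rny1. Calls covered 17977 clusters (48.3%), 9285 upward and 8692 downward. With quantile normalization they covered 5664 and 6241, with median centring 3135 and 14719, without the dimness filter 24221 and 9191, and with the hybridisation-control covariate 6 in all. Camera called erythroid (13 of 13 fell, median -3.14), proliferation (28 of 30 fell, -1.22), immediate-early (12 of 16 fell, -1.99) and type I interferon genes (13 of 32 fell, -0.34), with the same counts adjusted over the list alone. Their adjusted p were 1.27e-06, 5.3e-06, 0.000595 and 0.0398, and each had an adjusted p = 0.838 with an estimated correlation. The interferon call did not pass without control 21 d replicates 1 or 2 (adjusted p = 0.0551 and 0.0545), MEC1 21 d replicate 1 (0.0775), control 31 d replicates 1 or 2 (0.0566 and 0.0635) or MEC1 31 d replicate 3 (0.0901). With quantile normalization the interferon call did not pass (0.0669), and dendritic cell and progenitor genes passed downward (0.0211 and 0.037). With the covariate the medians of proliferation and interferon genes turned to 0.99 and 0.63, that of immediate-early genes was -0.08 and did not pass (adjusted p = 0.889), and Mir221 and Mir1938 turned to -0.45 and 0.06.

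The test of the difference between late and early disease called Il1r2 alone. Its change with MEC1 was larger at 31 days than at 21 days by 8.45 on the log2 scale (SE 0.646, adjusted p = 0.00203), and it was the 1 cluster of 37240 that passed, with 4793 at an unadjusted p under 0.05. At 21 days Il1r2 stood between 7.21 and 7.34 in MEC1 mice and between 7.31 and 8.13 in control mice. The control mean at 31 days, given above, lay below that control range. Part of the difference of 8.45 therefore lay in the control mice, and within MEC1 mice alone Il1r2 rose by 6.39. The genes with the next smallest p in each direction did not pass: Stfa2l1 at 3.80, the leukotriene dipeptidase Dpep2 at 2.00, the arginase Arg2 at 1.79 and the lectin Clec4d at 3.24 (adjusted p = 0.0835 each), Ighm at -3.78 (adjusted p = 0.101), Cd7 at -2.20, Pik3ca at -1.68, Depdc7 at -1.67 and Hsph1 at -4.40. With array weights 1573 clusters passed, 734 upward and 839 downward, with quantile normalization 17 and with 1 cluster per gene 13, and in the linear model without moderation 0 did, where Il1r2 had an adjusted p = 0.0877. Il1r2 passed in each fit that left out 1 array, with 5 clusters called without MEC1 21 d replicate 1, 2 without control 31 d replicate 1, and 3 and 4 without MEC1 31 d replicates 2 and 3. No list member passed over all clusters, but 7 lists differed by camera. Resident macrophage genes had a median difference of 0.50 and alternative activation genes of 0.34 (adjusted p = 0.00104 and 0.0201; adjusted p = 0.251 each with an estimated correlation), with 2 and 3 members higher adjusted over the list alone. Proliferation was lower by a median of -1.59 (21 members adjusted over the list alone), erythroid genes by -1.79 (4), immediate-early genes by -1.05 (2), the unfolded protein response by -0.98 (2) and progenitor genes by -0.86 (2). Their adjusted p were 3.44e-11, 0.000195, 0.0106, 0.00358 and 0.0034, and each had an adjusted p = 0.82 with an estimated correlation. On the deposited scale, progenitor and alternative activation genes were not called between the days within MEC1 mice. They were called in control mice, with medians of 0.365 and -0.097, so that part of these 2 differences may lie in the control mice. The alternative activation call did not pass without MEC1 31 d replicate 2 (adjusted p = 0.0831) or control 21 d replicate 2 (0.0515), nor the immediate-early call without control 31 d replicate 3 (0.06). Leaving out MEC1 31 d replicate 1 took the resident macrophage median to 0.11. The alternative activation median was 0.20 without MEC1 31 d replicate 2, control 21 d replicate 2 or MEC1 21 d replicate 1. The medians of the unfolded protein response and immediate-early genes were -0.56 and -0.59 without MEC1 31 d replicate 3, and that of erythroid genes -1.18 without MEC1 21 d replicate 3. With the hybridisation-control level as a covariate the medians of proliferation, progenitor and alternative activation genes were -0.38, -0.45 and 0.17 and passed, while those of the unfolded protein response and immediate-early genes were -0.04 and -0.09 and did not (adjusted p = 0.916 and 0.72).

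Between 21 and 31 days within MEC1 mice, 84 clusters changed, 51 upward and 33 downward. Separate mice were used on each day, and those at 31 days were older. The comparison therefore mixes the stage of the disease with age and with the day of tissue collection. It is to be read beside the same comparison in mice without MEC1, given below. Il1r2 rose by 6.39 (SE 0.457, adjusted p = 0.00101), Cxcl13 by 5.95 (SE 0.649, adjusted p = 0.0101) and Stfa2l1 by 4.06 (SE 0.361, adjusted p = 0.00475). Chil3, AW112010 and Saa3 rose by 3.75, 3.42 and 3.41. Ighm fell by 3.83 (SE 0.383, adjusted p = 0.00716), Hsph1 by 3.58, the non-coding RNA AI504432 by 2.35, the phospholipase D family gene Pld4 by 2.15, the mannosyltransferase Alg3 fell by 1.93 and the lectin-like receptor Klrb1f by 1.91. The count ranged from 7 without MEC1 21 d replicate 3 to 70 without MEC1 21 d replicate 1, with 11 without replicate 2, 14, 26 and 51 without control 21 d replicates 2, 3 and 1, 16, 22 and 32 without MEC1 31 d replicates 1, 2 and 3, and 21, 37 and 10 without control 31 d replicates 1, 2 and 3. With array weights it was 7735, of which 3372 were upward and 4363 downward, with quantile normalization 191, with the replicate number as a block 15 and with only the 6 arrays of MEC1 mice 1. Of the 12 genes, Il1r2, Stfa2l1 and Ighm passed in each fit that left out 1 array and the other 9 did not, with adjusted p of up to 0.167. Resident macrophage genes were higher at 31 days (median 0.47, 2 of 19 rose, 6 adjusted over the list alone, adjusted p = 3.35e-06; adjusted p = 0.116 with an estimated correlation). Camera also called lower medians for proliferation (-1.43), the unfolded protein response (-1.18), immediate-early genes (-1.31) and erythroid genes (-1.42), where 0, 0, 1 and 0 members fell over all clusters and 25, 11, 10 and 8 adjusted over the list alone (adjusted p = 0.666 each with an estimated correlation). Without MEC1 31 d replicate 3 the proliferation and immediate-early medians were -0.90 and -0.78, and without MEC1 21 d replicate 3 the immediate-early and erythroid medians were -0.81 and -0.82. With the covariate the medians of proliferation, the unfolded protein response and immediate-early genes were -0.38, -0.34 and -0.36. With quantile normalization neutrophil genes also passed upward (median 0.44, adjusted p = 0.028) and progenitor genes downward (adjusted p = 0.0164).

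In mice without MEC1, 3 clusters changed between the days, all downward. Here too, age and the day of tissue collection differed together. Vegfa, the vascular growth factor, fell by 1.63 (SE 0.13, adjusted p = 0.00318) and the membrane gene Emp1 by 2.76 (SE 0.306, adjusted p = 0.0277); the other had no single gene symbol. The count was 12 without control 21 d replicate 3, and 1 without control 21 d replicates 1 or 2, MEC1 21 d replicate 1 or control 31 d replicate 3. It was 266 with array weights, 10 with quantile normalization and 0 with only the 6 control arrays. Emp1 did not pass in 8 of the 12 fits that left out 1 array (adjusted p of up to 0.148). The genes with the next smallest p did not pass: Irs2 at -1.78, Errfi1 at -1.32, Fem1c at -1.61, Rnu12 at 1.00, Zfp780b at 0.96, AI987944 at 1.18, Mir5710 at 1.29 and Vwa8 at 0.80. By camera, 8 lists differed between the days. Inflammatory genes had a median of -0.39 at 31 against 21 days (0 of 21 fell, 5 adjusted over the list alone, adjusted p = 7.26e-06) and alternative activation genes of -0.10 (1 of 18 fell, adjusted p = 0.0354). Type I interferon genes had a median of 0.43 (adjusted p = 0.000712), and progenitor, neutrophil, basophil, platelet and stromal genes lay between 0.15 and 0.39 with no member passing. With an estimated correlation the adjusted p ran from 0.602 to 0.776 for the 8 lists. With quantile normalization proliferation genes also passed upward (median 0.34, adjusted p = 0.0274), and with the covariate neutrophil and basophil genes did not pass (0.418 and 0.159). Inflammatory and interferon genes passed in each fit that left out 1 array, with inflammatory medians of -0.21 without control 21 d replicate 2 or control 31 d replicate 1 and an interferon median of 0.28 without control 21 d replicate 1. The other 6 did not, with adjusted p of up to 0.347 (stromal genes without control 21 d replicate 3), 0.326 (platelet) and 0.114 (progenitor) without control 31 d replicate 1, 0.147 (neutrophil) without control 21 d replicate 1, 0.0993 (basophil) without control 21 d replicate 3 and 0.131 (alternative activation) without control 21 d replicate 2. Without control 31 d replicate 1 the medians of progenitor, platelet, basophil and stromal genes were 0.19, 0.15, 0.21 and 0.05, and without control 21 d replicate 1 that of neutrophil genes was 0.16. The alternative activation median was -0.05 without control 21 d replicate 2 and -0.16 without control 31 d replicate 1.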

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

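The tests of less labelled target, of less total RNA, of microRNA precursors, of erythroid genes, of the array in which the rises were highest and of neutrophils were chosen only after the results or some of the values they use were seen, as were the hybridisation-control covariate and the comparison with matched random lists, while the limits for the mRNAs with ultraconserved exons were written before any of their values was seen.

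The change of Il1r2 with MEC1 differed between the days by 8.45 on the log2 scale in the test of the difference itself, 7.97 at 31 days against -0.48 at 21 days. Il1r2 was higher than in every control array in 3 of 3 MEC1 mice at 31 days. Its control mean was lower at 31 than at 21 days, and within MEC1 mice alone it rose by 6.39. Among the lists, camera found differences between the days of 0.503 for resident macrophage genes, 0.337 for alternative activation, -1.59 for proliferation, -1.79 for erythroid genes, -1.05 for immediate-early genes, -0.975 for the unfolded protein response and -0.855 for progenitor genes. None of these 7 passed with an estimated correlation. On the deposited scale, progenitor and alternative activation genes were called between the days in control mice but not within MEC1 mice. Leaving out 1 array took the resident macrophage median to 0.11 (MEC1 31 d replicate 1), alternative activation to 0.20 (MEC1 31 d replicate 2, MEC1 21 d replicate 1 or control 21 d replicate 2), the unfolded protein response and immediate-early genes to -0.56 and -0.59 (MEC1 31 d replicate 3) and erythroid genes to -1.18 (MEC1 21 d replicate 3). With the hybridisation-control covariate the differences were -0.38 for proliferation, -0.45 for progenitor genes, -0.04 for the unfolded protein response and -0.09 for immediate-early genes, of which the last 2 did not pass.

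The first pattern is the difference of the MEC1 arrays as a whole, seen in control features outside the main measurement: hybridisation controls were higher by 1.53 and poly-A controls by 0.864. The rise of the poly-A controls argues against less labelled target with unchanged RNA, while less total RNA stays open: the 16 small nuclear, 7SL and Y RNA clusters had a median change of 2.03, but that set was chosen after members of it were seen among the largest rises. Human RNA from MEC1 cells in the purified fraction may contribute: microRNA precursors numbered under 500, most of them shared among mammals, rose more than the others by 0.202 (medians 0.457 and 0.255, 175 and 424 precursors, permutation p = 9e-05). They were also dimmer (mean level 5.49 against 5.78). Within bins of similar level the difference was 0.202 over all arrays (permutation p = 4e-05) and 0.134 by the level in control arrays (permutation p = 0.0055). It was 0.18 (permutation p = 0.00033) without the 4 precursors seen among the rises before the test was chosen. These permutations moved the labels among precursors, not among mice. The p-values therefore take precursors of the same arrays as independent and do not measure the spread between mice. A test on 28 mRNAs with ultraconserved exons stayed undecided (percentile 96.61 of matched lists, short of the limit set in advance), and a change of mouse RNA with leukemia stays open and untested, since the groups explain 92.1% of the variance of the hybridisation controls.

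The second pattern is the fall of the erythroid genes at 31 days. Their median of -3.98 lay below all 10000 random lists of matched level (percentile 0, central 95% from -1.34 to -0.307), which argues against the array-wide loss of signal as the whole account. Fewer erythroid cells carried over with the purified cells and a lower output of red cells in leukemic marrow both stay open. All measured members, 100%, also fell after quantile normalization, but their fall was known when this test was chosen, so it decides between neither. The proportion of cells was not measured.

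The third pattern is the set of the 12 largest rises at 31 days. If human RNA read by the mouse probes were the source, they could be highest in replicate 3, which had the highest hybridisation controls. Of the 7 genes that were not small RNAs 1 was (Traj14), and of the 5 small RNA genes 3 were (Rnu6, Mir221 and Mir103-2). Both counts are within what chance of 1 in 3 per gene allows, so neither decides. That reckoning takes the genes as independent, although they were read on the same arrays and Rn7s1 and Rn7s2 held identical values. Carry-over of neutrophils stays undecided too, with the neutrophil list at the 86.71 percentile of matched lists (median 0.00757). Induction of Il1r2, Cxcl13 and Saa3 in the myeloid cells by leukemia stays open as the biological explanation that the design names.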

How the results depend on the processing

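The hybridisation-control covariate and quantile normalization without MEC1 31 d replicate 3 were chosen after seeing the data, and the other alternatives were planned. Of 7228 values of 282 gene results, 6313 kept their direction and side of the threshold, 717 no longer passed, 138 newly passed and 60 reversed. Of 726 values of 33 list results, 595 were the same, 125 no longer passed and 6 reversed. Of 154 values of the 6 counts, 83 stayed within 1.5 times and 71 moved. Camera with an estimated correlation ended all 33 list calls and fry ended 20. The covariate left 58 of 282 gene results the same, ended 169 and reversed 53. The groups explain 92.1% of its variance and it inflates the variance of the 31-day contrast by 9.71, so a loss of calls follows from its construction, while the cause of the reversals was not tested. Apart from it, few gene directions reversed: Itgb3 and Cd79b, neither of which passed. Signal over background limited what could be tested: Ms4a1 was too dim. In the counts below the cause was not tested, except that 1 cluster per gene and the 70th percentile filter test fewer clusters, no filter tests more, and the 6 arrays and left-out arrays use fewer arrays.

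At 21 days the count was 1066 with quantile normalization, 15923 with array weights, 454 with the 6 arrays of the comparison, 676 without moderation and 4 with the covariate, against 1615. At 31 days, against 16297, it was 30065 with no filter, 10483 with the 70th percentile filter, 10646 with quantile normalization, 10636 with 1 cluster per gene, 10622 with their average, 7 with the covariate and 7140 with quantile normalization without MEC1 31 d replicate 3. For the average, against 17977, these were 33412, 11519, 11905, 11087, 11066, 6 and 10418, and 11585 with a 1.5-fold minimum. For the difference, against 1, they were 17 with quantile normalization, 1573 with array weights, 13 with 1 cluster per gene, 13 with their average, 0 without moderation, 4 with the covariate and 16 with quantile normalization without that replicate. Between the days in MEC1 mice, against 84, they were 191 with quantile normalization, 20 with arrays centred, 7735 with array weights, 1 with the 6 arrays, 25 without moderation and 10 with the covariate. Between the days in control mice, against 3, they were 10 with quantile normalization, 266 with array weights, 0 with the 6 arrays, 1 without moderation, 15 with the covariate and 15 with quantile normalization without that replicate.

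The replicate block, which treats equal mouse numbers as pairs, gave 831 at 21 days and 15 between the days in MEC1 mice. Arrays with the same number correlated in their deviations at 0.363, -0.169 and 0.415 at 21 days and at -0.011, 0.16 and 0.018 at 31 days. Arrays with different numbers correlated between -0.49 and 0.328 at 21 days and between -0.153 and 0.107 at 31 days. With 3 pairs per day these values do not decide whether the numbers pair the mice.

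Leaving out each array in turn gave counts of 333 to 2875 at 21 days, 10556 to 16599 at 31 days, 14248 to 18768 for the average, 1 to 5 for the difference, 7 to 70 between the days in MEC1 mice and 1 to 12 in control mice.

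With the covariate, values at 21 days reversed to 2.25 for Ly6c2, 0.16 for Itgam, 0.43 for Csf1r, 0.11 for Cd68, 0.052 for Adgre1, -0.37 for Cd79b, -0.50 for Cd79a, 0.60 for Stat2, -0.27 for Nos2, 0.27 for Ccl3, 0.16 for Tk1, 0.66 for Mcm2, 0.65 for Insig1, 0.019 for Atf3, 0.086 for Itgb3, 0.65 for Cd177, 1.58 for Prss34, 0.29 for Kit, 1.52 for Neat1 and 0.22 for the immediate-early list. At 31 days they reversed to -0.72 for Mir221, 2.94 for Ly6c2, 1.18 for Itgam, 1.01 for Csf1r, 0.48 for Cd68, 0.59 for Adgre1, -0.77 for Cd79a, 1.18 for Stat2, 0.054 for H2-DMb1, 1.07 for Ccl3, 0.65 for Tgfb1, 0.37 for Cenpe, 0.14 for Mcm5, 0.24 for Vsir, 1.12 for Sqle, 1.30 for Insig1, 0.14 for Atf3, 0.96 for Hspa5, -0.040 for Chac1, 1.48 for Mcpt8, 1.91 for Prss34, 0.69 for Itgb3, 0.15 for Norad, 2.66 for Neat1 and 2.57 for Malat1. The list medians reversed to 0.88 for interferon genes, 0.80 for proliferation and 0.83 for the unfolded protein response. For the average they reversed to -0.45 for Mir221, 0.062 for Mir1938, 2.60 for Ly6c2, 0.67 for Itgam, 0.71 for Csf1r, 0.29 for Cd68, 0.32 for Adgre1, -0.85 for Cd79b, -0.63 for Cd79a, 0.63 for the interferon list and 0.99 for proliferation.

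Itgb3 at 31 days became 0.068 with quantile normalization and 0.24 with quantile normalization without MEC1 31 d replicate 3. The average of Cd79b became -0.27 with arrays centred and -0.081 with array weights. It became -0.0058 without control 21 d replicate 3, -0.0225 without MEC1 21 d replicate 1 and -0.037 without MEC1 31 d replicate 3. The last was the lowest of the fits that left out 1 array, which reached 0.123 without MEC1 31 d replicate 1.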

Other observations

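The splits of the arrays were planned, while the small RNA genes, Xist, Tsix and the Y-linked genes were chosen after their values were seen.

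Levels of marker lists were compared between groups within each list, since levels of different probes cannot be ranked. The median erythroid level was 10.14 ± 0.426 in control mice and 5.587 ± 0.255 in MEC1 mice at 31 days (SD, n = 3), while at 21 days MEC1 mice stood at 7.573 ± 1.62. Classical monocyte genes stood at 12.60 ± 0.15 and 12.11 ± 1.28. Neutrophil genes stood at 11.00 ± 0.283 and 9.415 ± 1.44, B cell genes at 4.197 ± 0.121 and 4.697 ± 0.238, and platelet genes at 4.457 ± 0.202 and 4.697 ± 0.0252.

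Small structural RNAs did not all move with the 7SL RNA. Averaged over both days, the U6 gene Rnu6 rose by 3.89, the U11 gene Rnu11 by 2.40 and the U2 gene Rnu2-10 by 1.47, whereas the U12 gene Rnu12 fell by 0.30. Rn7sk, the 7SK RNA that restrains transcription elongation, had a change of -0.18 that did not pass (adjusted p = 0.0781).

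Xist stood at 5.49, 13.49 and 10.61 in the 3 MEC1 mice at 31 days and between 14.33 and 16.17 in the other 9 mice. The Y-linked genes were dim in all 12 mice but higher in each MEC1 mouse than in any control mouse. Kdm5d lay between 3.73 and 4.31 against 3.44 to 3.56, Eif2s3y between 4.21 and 4.90 against 3.93 to 4.14, and Uty between 4.02 and 4.72 against 3.74 to 3.96. Dim clusters rose in general: those at or below a control level of 4 had median changes of 0.26 at 21 days and 0.53 at 31 days. Those from 4 to 5 had medians of 0.12 and 0.28. Part of the Y-linked rises may be this shift of dim clusters. Tsix, the antisense transcript of Xist, lay between 4.78 and 5.03 in MEC1 mice and between 5.45 and 6.12 in control mice. Apart from the fall of Xist at 31 days, given above, no test of these differences is reported here.

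Other splits of the same arrays were fitted. At 21 days the real split called 1615 clusters and the highest other split 179, at 31 days 16297 and 0, within MEC1 mice 84 and 0, and within control mice 3 and 1. In each of these only 1 of 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05. For the average, 1 of 100 drawn splits, the real one, called as many as 17977, although another split called 17142. This share is under 0.05, which argues against chance. It is also the smallest share that 100 splits can give, so chance is not excluded. For the difference, 14 of 100 called at least the 1 cluster of the real split, up to 11127, so this share does not exclude chance. It is no test of the difference, however, because 12 of the other splits kept the 31-day groups and with them the 31-day change. Those 12 called between 1 and 17142 for the average and between 1 and 11127 for the difference, while the other 87 called 0 and between 0 and 10. The many calls point to the structure of the 31-day groups.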
